A study of Mus musculus with 6 samples.

How the data were processed

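Whole-brain RNA was measured in 7-day-old male C57BL/6J mice, an inbred laboratory strain, that had received ethanol or saline under the skin. Per the labels' protocols and the series design text, ethanol was given as a 20% solution in 2 doses of 2.5 g/kg, and brains were collected 4 h after the first dose. The 2 doses were 2 h apart. RNA of 3 males from different litters was pooled in equal amounts for each array, and 200 ng of the pool was labelled for an Affymetrix whole-transcript array, per the labels' protocols. There were 2 ethanol pools and 4 saline pools, from 18 mice. The arrays are numbered as in the labels, with ethanol on arrays 2 and 4 and saline on arrays 1, 3, 5 and 6.

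The authors deposited 1 value per probeset and array. The deposited values were taken to be on a log2 scale from their range, which was 4.10 to 14.9, since the log base is not stated in the labels. Partek 6.6 was used, per the submitters' processing notes. The background correction, normalization and summarisation behind the values are not given in the sources used here, so the values were used as deposited in the main fit. A different normalization could move small changes that go one way across the array, and for that reason 2 other scalings were tried.

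The table held 35556 probesets. The platform annotation paired 21789 of them with 1 gene symbol and 1621 with several, and 12146 were unnamed here. Of those with 1 symbol, 21698 matched a current gene record, from which symbols were updated. Probesets with several symbols were not used to name genes. The named probesets covered 19939 genes, of which 998 had more than 1 probeset. Each such gene was represented by the probeset with the highest mean over all 6 arrays. The dimmest 25% of genes by that mean (4985 genes, up to 5.55 on the log2 scale) were left out, and 14954 genes were tested. As a guide to background, 1194 olfactory and vomeronasal receptor genes had a median of 5.35 and a 95th percentile of 6.21, and 2420 tested genes had a mean below that percentile. Genes named below that level are said to be near background. No genomic coordinates are given, because the genome build behind the array annotation was not matched to a reference.

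Each gene was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with treatment as the only term and all 6 arrays in the fit. The test was two-sided, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 4 residual degrees of freedom, and the prior estimated across genes added 8.10. Ethanol pups had littermates among the saline pups, per the series design text, but no number is shared between the groups, so no litter or pair term could be fitted. Replicates are pools from separate animals, and the p-values measure the spread between pools. The number of arrays limits the precision of each value.

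Gene lists were fixed before the data were examined, as were the groups, the tests, the processing alternatives and the rule for named genes. There were 43 lists, of pathways fit for an acute ethanol dose and of markers of cell types and tissues that a brain dissection can hold. Of these, 42 had at least 5 tested members (23 pathway and 19 cell type lists), and the list of pineal and retinal markers had too few and was not tested. Of the listed genes, 748 entries were tested, 80 were dim, 19 lay on probesets of several genes, 1 had no match and 58 were not analysed here. Each list was compared with all other genes by limma's camera test with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 42 lists. Camera was repeated with an estimated correlation, a setting in which it also uses only the 4 residual degrees of freedom of the fit. Fry, which asks whether the members move on balance one way, was run beside it. It tests the members on their own, without comparison with other genes. For each list, members were also counted with the gene p-values adjusted over the list alone. The mean level of each list per array was set against the 15 ways of choosing 2 of 6 arrays in an exact permutation test, where the smallest possible p is 0.0667, so that this test cannot pass the threshold.

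The genes named are those that passed the threshold with both ethanol arrays beyond all 4 saline arrays, up to 12 in each direction by size. Places left were filled with the genes of smallest unadjusted p in that direction, and these are said not to have passed. From each fixed list up to 4 members with the smallest unadjusted p were named, which was narrowed after the results were seen to 4 where the list or a member had passed, 2 for other pathway lists and 1 for other cell type lists. Y-linked genes and Xist were read as a check of the stated sex. Predicted genes and small RNAs were to be given only by count, and none had passed.

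Alternatives were no filter on dim genes, a filter of the dimmest 50%, the mean of a gene's probesets, and every probeset that was not dim (26049 of 35556). Further ones were a variance prior with a trend, a robust prior, no prior, quantile normalization, centring of each array on its median, and array weights. Each array was also left out in turn, and 2 other thresholds were tried. Without 1 ethanol array, the remaining one was assumed to vary like the saline group. Removing the genes that passed from the called lists, and members of fixed lists or genes with an adjusted p under 0.10 from 2 added lists, was added after the data were seen.

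The fit and the list test were tested on simulated data with 14954 genes, 2 against 4 arrays and 200 changed genes, in 5 runs. Of genes changed by 0.25 on the log2 scale 22.4% were recovered, of those changed by 0.5 94.8%, by 0.75 99.2% and by 1 100%. Noise was drawn independently for each gene from the fitted prior, and 200 genes were changed, where 12 passed in the data. These shares therefore do not measure recovery in the data, where Bcl2l11, at a change of 0.53, did not pass. Of all calls, 3.89% were unchanged genes and 0 had the wrong sign. A list of 25 genes shifted by 0.15 was called by camera in 5 of 5 runs, and 0 unshifted lists were called per run. The simulated lists held random genes with independent noise, so their members did not vary together. In the data the 3 called lists had estimated correlations of 0.218 to 0.242, so these runs do not test false calls of such lists.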

Results

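Gene expression was measured in the whole brain of 7-day-old male C57BL/6J mice given ethanol or saline, on 2 ethanol arrays and 4 saline arrays. Every array held RNA pooled from 3 pups. Levels are log2 intensities, given as mean ± SD, and changes are log2 differences, ethanol minus saline, given with the standard error (SE) of the limma fit over these 2 and 4 arrays. The number of arrays limits the precision of each value. The Y-linked genes Kdm5d, Uty and Eif2s3y had mean levels of 8.83, 9.30 and 10.5 over the 6 arrays, and their lowest values on any array were 8.81, 9.15 and 10.4. Xist, which is transcribed from the inactive X chromosome of females, lay between 4.83 and 5.13, within the background range. Over the 14954 tested genes, pairs of arrays correlated with r of 0.995 to 0.999, a value across genes, which are not independent replicates. The median of tested genes was 8.34 and 8.35 on ethanol arrays 2 and 4, and 8.37, 8.29, 8.38 and 8.38 on saline arrays 1, 3, 5 and 6. Saline array 3 stood apart on the first principal component, which held 40.9% of the variance, at 13.5. Saline arrays 1, 5 and 6 lay at -2.13, 2.95 and -0.19 on it. Ethanol arrays 2 and 4 lay at the end opposite to saline array 3, at -6.61 and -7.49.

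The comparison of ethanol with saline pools addressed which brain transcripts differ 4 h after the first ethanol dose. Txnip, whose product binds thioredoxin and restrains glucose uptake, rose 2.56-fold, from 9.42 ± 0.26 (SD, n = 4) to 10.8 ± 0.08 (SD, n = 2). The related arrestin-domain genes Arrdc3 and Arrdc4 rose by 103% and 50.2%. Jun, a subunit of the AP-1 transcription factor, rose 2.32-fold, from 9.18 ± 0.26 to 10.4 ± 0.13. Dusp6, the phosphatase that inactivates ERK, fell to 0.614 of its saline level, from 8.84 ± 0.10 to 8.13 ± 0.02. In all, 12 genes passed the limma test, 9 higher and 3 lower with ethanol, and for each of them both ethanol arrays lay beyond all 4 saline arrays.

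The log2 changes of the leading genes were 1.35 ± 0.13 (SE) for Txnip (limma adjusted p = 0.00151), 1.22 ± 0.13 for Jun (0.00211), 1.02 ± 0.10 for Arrdc3 (0.00151) and 0.59 ± 0.08 for Arrdc4 (0.0249). Dusp1, a phosphatase of the p38 and JNK kinases, rose by 0.67 ± 0.09 (limma adjusted p = 0.0149), and Btg2, an antiproliferative gene, by 0.57 ± 0.06 (0.00211). Mertk, a receptor kinase with which phagocytes take up dying cells, rose by 0.59 ± 0.09 (limma adjusted p = 0.0382). Pik3ip1, an inhibitor of PI3-kinase, rose by 0.54 ± 0.08 (limma adjusted p = 0.0435), and the zinc finger gene Zfp975 by 0.82 ± 0.13 (0.0386). Besides Dusp6, with a log2 change of -0.70 ± 0.07 (limma adjusted p = 0.00151), the genes that fell were Ltv1, a 40S ribosome assembly factor (-0.63 ± 0.08, 0.0149), and Nr4a1, an orphan nuclear receptor induced by activity (-0.47 ± 0.06, 0.0104). Txnip, Arrdc3, Btg2 and Dusp6 passed whichever array was left out. Of the other 8, all lost the call without ethanol array 4 (adjusted p of 0.112 for Jun and Pik3ip1, 0.214 for Nr4a1, 0.270 for Dusp1, Ltv1 and Arrdc4, 0.302 for Zfp975 and 0.386 for Mertk in limma). Their log2 changes in that fit, with 1 ethanol array left, were 1.12 for Jun, 0.65 for Pik3ip1, -0.45 for Nr4a1, 0.62 for Dusp1, -0.59 for Ltv1, 0.59 for Arrdc4, 0.85 for Zfp975 and 0.51 for Mertk. Without ethanol array 2, adjusted p in limma was 0.0803 for Nr4a1 and Dusp1, 0.0917 for Ltv1, 0.155 for Arrdc4, 0.181 for Zfp975, 0.0941 for Mertk and 0.197 for Pik3ip1. Saline arrays ended calls only for Zfp975 (0.159 without array 5), Mertk (0.0510 without array 1 and 0.128 without array 5) and Pik3ip1 (0.0647, 0.0953 and 0.0564 without arrays 1, 3 and 6), as adjusted p in limma. After centring of the arrays 8 genes passed, 7 higher and 1 lower, without Zfp975, Pik3ip1, Ltv1 and Nr4a1. In limma 0 passed over every probeset that was not dim or with no variance prior, with 2570 and 1535 at an unadjusted p under 0.05.

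**Figure D1:**
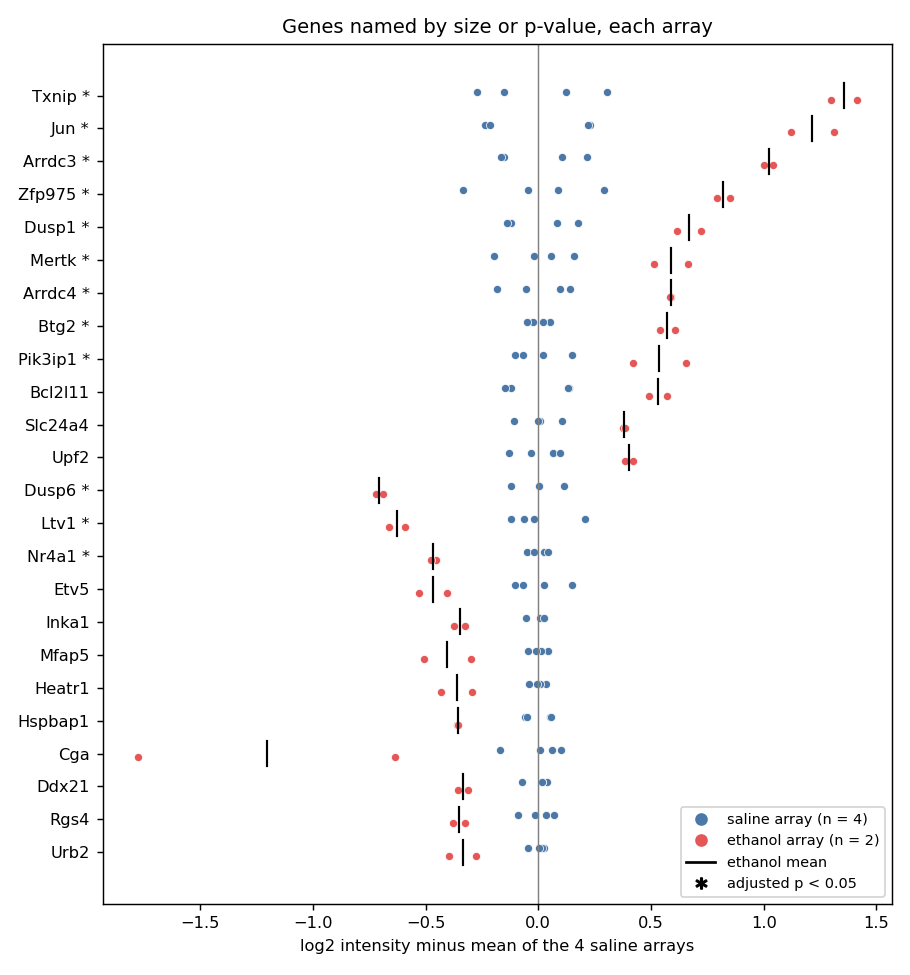
Log2 intensity of each array minus the mean of the 4 saline arrays (horizontal axis) for 24 genes named by size or p-value (rows), with blue points for saline arrays, red points for ethanol arrays, a black bar for the ethanol mean and a star for genes that passed. Both ethanol points of Txnip lie near the change of 1.35, and those of Cga, which did not pass, lie far apart at levels of 7.19 and 6.06, the lower one within background.

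Genes with the next smallest p-values did not pass, and each had a limma adjusted p of 0.0631. On the higher side these were Bcl2l11, which encodes the pro-apoptotic protein BIM (log2 change 0.53 ± 0.09), Slc24a4 (0.38 ± 0.07) and Upf2, a nonsense-mediated decay factor (0.40 ± 0.07). On the lower side were the ETS factor Etv5 (-0.47 ± 0.08), the pituitary hormone subunit gene Cga (-1.20 ± 0.21) and the G-protein regulator Rgs4 (-0.35 ± 0.06). The nucleolar genes Heatr1, Ddx21 and Urb2 had log2 changes of -0.36 ± 0.06, -0.33 ± 0.06 and -0.34 ± 0.06. Hspbap1 had -0.36 ± 0.06, and the near-background genes Inka1 and Mfap5 had -0.35 ± 0.06 and -0.40 ± 0.07. A further probeset of Etv5 gave -0.64. At an unadjusted p under 0.05 there were 1838 genes, 575 higher and 1263 lower, or 12.3% of tested genes where chance gives 5%. Both ethanol arrays lay beyond all saline arrays for 3384 genes (1148 higher and 2236 lower), or 22.6%, where chance gives 13.3%. Genes on an array vary together, so a single split can lie far from these chance shares without a treatment effect. The shares for other splits of the arrays are not given here.

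Immediate early and activity-regulated genes moved both ways. Of 30 tested members, Jun, Dusp1 and Btg2 rose and Dusp6 and Nr4a1 fell among all genes, and 25 did not pass. With p-values adjusted over the list alone, 4 members were higher and 7 lower. The list median was -0.08, with 21 members below 0, and the list as a whole was not shifted against other genes (camera adjusted p = 0.521). Among neurotrophins and growth factor signalling genes (22 tested), the ERK pathway inhibitor Spry4 had a log2 change of -0.49 ± 0.10 and Igfbp3 one of 0.35 ± 0.08. They were the 1 lower and 1 higher member adjusted over the list alone, none of the list passed among all genes in limma, 7 had an unadjusted p under 0.05, and the list's camera adjusted p was 0.875.

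Glucocorticoid-responsive genes were higher with ethanol as a group, with a median log2 change of 0.10 over 25 tested members, 19 of them above 0 (camera adjusted p = 5.05e-08; adjusted p = 0.950 with an estimated correlation). Mertk alone rose among all genes, and 9 members were higher and 0 lower adjusted over the list alone (limma, with 11 higher and 0 lower at an unadjusted p under 0.05). Below Mertk in p-value were Hif3a, near background (0.29 ± 0.07), Ddit4, an inhibitor of mTORC1 (0.28 ± 0.07), and Klf9, a hormone-induced transcription factor (0.25 ± 0.07). The mean level of the list was 8.20 and 8.24 on ethanol arrays 2 and 4, and 8.05, 8.05, 8.13 and 8.13 on saline arrays 1, 3, 5 and 6.

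Genes of fasting and FoxO transcription were also higher as a group, with a median of 0.11 over 20 tested members (camera adjusted p = 1.39e-05, or 0.950 with an estimated correlation). Of these members, 13 lay above 0 and 7 below. Txnip and Pik3ip1 rose among all genes, and 5 members were higher and 1 lower adjusted over the list alone. Foxo3, a FoxO factor itself, had a log2 change of 0.42 ± 0.08 (limma adjusted p = 0.0723), and Pdk2, a kinase that restrains pyruvate dehydrogenase, 0.22 ± 0.07 (0.232). Mean levels of the list were 8.56 and 8.53 on ethanol arrays 2 and 4 and 8.35, 8.31, 8.42 and 8.43 on saline arrays 1, 3, 5 and 6. The glucocorticoid and FoxO lists share 3 tested genes. In the intrinsic apoptosis list, Bcl2l11 (0.53 ± 0.09) and the stress-induced Sesn1 (0.37 ± 0.07) led 30 tested members. None passed among all genes in limma, 7 had an unadjusted p under 0.05, and 4 were higher and 1 lower adjusted over the list alone. That list had a camera adjusted p of 0.0755, which became 0.0204 with no filter on dim genes and 0.0437 with array weights.

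**Figure D2:**
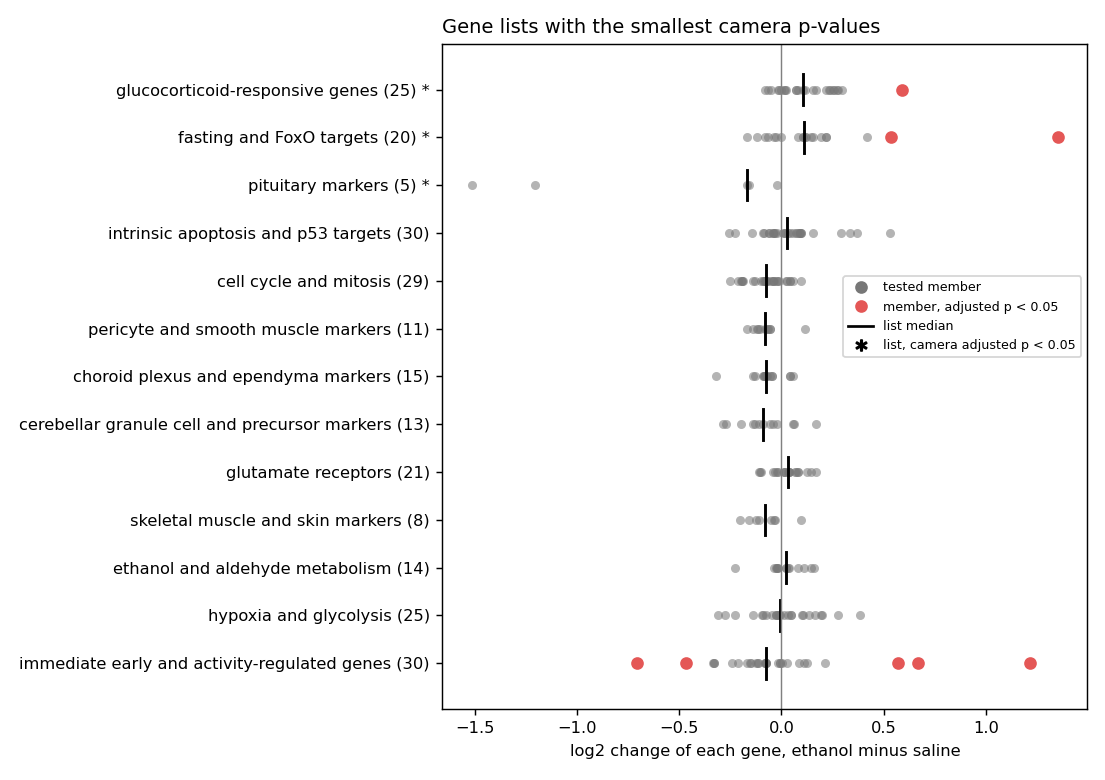
Log2 change, ethanol minus saline (horizontal axis), of each tested member (points) of the 13 lists with the smallest camera p-values (rows, number of tested members in brackets), with red points for members that passed among all genes, a black bar for the list median and a star for lists that passed. The glucocorticoid and FoxO lists have medians of 0.10 and 0.11, and the immediate early list has passing members on both sides of 0.

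Genes of hypoxia and glycolysis went both ways. The glucose transporter gene Slc2a1 had a log2 change of 0.38 ± 0.08 (limma adjusted p = 0.0838) and the angiogenic factor gene Vegfa -0.28 ± 0.06 (0.0904). Of 25 tested members, 4 were higher and 3 lower adjusted over the list alone, none passed among all genes in limma, 9 had an unadjusted p under 0.05, and the camera adjusted p was 0.521. In the antioxidant list (22 tested), Txnip rose, and Sod3, Gsr and Prdx1 had changes of -0.23 ± 0.07, -0.18 ± 0.06 and -0.16 ± 0.07 (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.875). Another probeset of Prdx1 gave -0.09. Circadian clock genes (18 tested) had 1 higher and 3 lower members adjusted over the list alone and none among all genes in limma, with 7 at an unadjusted p under 0.05. Per2 and Cry1, which repress the clock's own activators, had changes of -0.33 ± 0.06 and -0.26 ± 0.06, and the list had a camera adjusted p of 0.875. Cell cycle and mitosis genes had a median of -0.07, with 23 of 29 members below 0, and were led by Aurka (-0.25 ± 0.08) and Bub1 (-0.19 ± 0.06). None of them passed adjusted over the list alone or among all genes in limma, 6 were lower at an unadjusted p under 0.05, and the camera adjusted p was 0.190. It became 0.0162 with the dimmest 50% of genes left out and 0.00125 without ethanol array 2.

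Stress and inflammation lists were not shifted in camera. Fry's mixed test counts changes in either direction and does not compare a list with other genes. In it the unfolded protein (fry mixed adjusted p = 0.0231), heat shock (0.0442) and cytokine lists (0.0133) passed, and the interferon list (0.662) did not. In the unfolded protein and integrated stress response (34 tested, camera adjusted p = 0.875), the chaperone cofactor gene Sdf2l1 had a change of -0.39 ± 0.12 and Eif2ak3, which encodes the ER stress kinase PERK, 0.23 ± 0.08. No member passed adjusted over the list alone, and 9 had an unadjusted p under 0.05 in limma. Heat shock genes (19 tested, 0.855) had 1 lower member adjusted over the list alone, Chordc1 at -0.29 ± 0.06, while Dnajb4 had 0.18 ± 0.08. Cytokines and acute inflammation genes (16 tested, 0.650) had 2 lower members adjusted over the list alone, the chemokine genes Ccl3 (-0.30 ± 0.07) and, near background, Ccl7 (-0.22 ± 0.07). In the interferon response (13 tested, 0.789), Oasl2 had -0.13 ± 0.07 and Stat2 0.10 ± 0.06, and 0 members passed or had an unadjusted p under 0.05 in limma. Among all tested genes, none of these 4 lists held a gene that passed in limma, with 9, 4, 3 and 0 members at an unadjusted p under 0.05.

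Metabolic and growth lists were likewise not shifted in camera. Genes of ethanol and aldehyde metabolism (14 tested, camera adjusted p = 0.474) were led by Aldh1b1 (0.16 ± 0.08) and the alcohol dehydrogenase gene Adh1 (-0.23 ± 0.11), with 0 members at an unadjusted p under 0.05 in limma. Oxidative phosphorylation (29 tested, 0.521) was led by Ndufa4 (0.11 ± 0.06) and Ndufa9 (-0.11 ± 0.06), also with 0. Cholesterol synthesis (20 tested, 0.875) was led by Idi1 (-0.26 ± 0.08, with another probeset at -0.29) and Msmo1 (-0.19 ± 0.06), with 2 higher and 2 lower members at an unadjusted p under 0.05. Ribosomal protein genes (21 tested, 0.875) had 1 lower member adjusted over the list alone, Rpl12 at -0.44 ± 0.09 and the 1 with an unadjusted p under 0.05, and Rps3 had -0.08 ± 0.06. Retinoid signalling (16 tested, 0.875) was led by Rbp4 (-0.19 ± 0.06) and Rarg (0.17 ± 0.07), with 3 such members, and chromatin and DNA methylation enzymes (26 tested, 0.855) by Hdac9 (-0.19 ± 0.06) and Tet1 (0.13 ± 0.06, with other probesets at 0.14 and 0.11), with 2. Apart from Rpl12, no member of these 6 lists passed adjusted over the list alone, and none passed among all genes in limma.

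Synaptic gene lists did not differ detectably between the groups. The NMDA receptor subunit genes Grin2a and Grin2b, the leading members of 21 tested glutamate receptor genes, had changes of 0.17 ± 0.08 and 0.15 ± 0.07 (camera adjusted p = 0.332). In GABA signalling (19 tested, 0.855), Gabrb1 had 0.11 ± 0.06 and the vesicular transporter gene Slc32a1 -0.11 ± 0.07. Synaptic vesicle and active zone genes (24 tested, 0.764) were led by Snap25 (-0.19 ± 0.06) and Cplx1 (-0.09 ± 0.06). Postsynaptic density genes (25 tested, 0.789) were led by Cacng3 (-0.16 ± 0.06) and Cacng2 (-0.13 ± 0.06, with another probeset at 0.03). None of these members passed in limma, adjusted over the list alone or among all genes, and the 4 lists held 1, 0, 1 and 1 members at an unadjusted p under 0.05.

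Pituitary markers were lower with ethanol as a group of 5 tested genes, all below 0, with a median of -0.17 (camera adjusted p = 0.00678; adjusted p = 0.950 with an estimated correlation). Growth hormone (Gh) went from 8.20 ± 0.36 (SD, n = 4) to 6.69 ± 1.37 (SD, n = 2), a log2 change of -1.52 ± 0.38 (SE, limma adjusted p = 0.162), and Cga, the subunit shared by thyrotropin and gonadotropins, from 7.83 ± 0.12 to 6.62 ± 0.81. They were the 2 lower members adjusted over the list alone, and none passed among all genes in limma, with 4 lower at an unadjusted p under 0.05. On ethanol array 4, Gh at 5.72 and Cga at 6.06 lay within the background range (up to 6.21), so their ethanol means and changes rest partly on values at background. Fshb, near background, had -0.17 ± 0.08 and Ghrhr -0.16 ± 0.07. The ethanol arrays differed, with Gh at 7.65 on array 2 and at background on array 4, and saline arrays 1, 3, 5 and 6 had 8.39, 7.70, 8.20 and 8.52. Without saline array 3 the list's camera adjusted p was 0.0835, and without ethanol array 2 it was 5.10e-06.

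**Figure D3:**
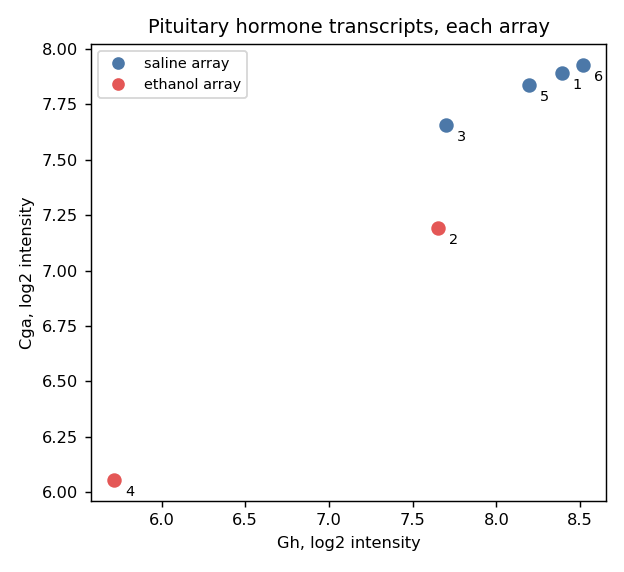
Log2 intensity of Cga (vertical axis) against that of Gh (horizontal axis) on each array, with saline arrays in blue, ethanol arrays in red and the array number beside each point. Ethanol array 4 lies lowest on both axes, at 5.72 for Gh and 6.06 for Cga, both within background, and saline array 3 lies near ethanol array 2 on the Gh axis, at 7.70 and 7.65.

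Markers of the other cell types and tissues were not shifted in camera, with adjusted p of 0.296 or more for all 18 lists. Oligodendrocyte precursor (fry mixed adjusted p = 0.00931), inhibitory neuron (0.0298), pericyte (0.0442) and striatal neuron markers (0.0452) passed fry's mixed test. That test does not compare a list with other genes. In limma, 3 of 12, 3 of 16, 1 of 11 and 1 of 9 of their members had an unadjusted p under 0.05, against 12.3% of all tested genes. Oligodendrocyte precursor markers (12 tested) had 1 lower member adjusted over the list alone, the lineage factor Olig2 at -0.32 ± 0.07. Choroid plexus and ependyma markers (15 tested) also had 1, Sostdc1 at -0.32 ± 0.07, as had striatal neuron markers (9 tested), Isl1 at -0.21 ± 0.06, and skeletal muscle and skin markers (8 tested), Acta1 at -0.20 ± 0.06. Cerebellar granule cell and precursor markers (13 tested) had 2 lower members adjusted over the list alone, and Barhl2 had -0.27 ± 0.07. Among neuronal lists with none, Neurod6 led excitatory neurons (-0.18 ± 0.06), Pvalb inhibitory neurons (-0.20 ± 0.07), Skor2 Purkinje cells (-0.18 ± 0.07), Gal hypothalamic peptides (-0.23 ± 0.07) and Th the olfactory bulb (0.29 ± 0.10). Glial and vascular lists were led by S100b for astrocytes (-0.18 ± 0.06), Fcrls for microglia and macrophages (-0.20 ± 0.08), Mog for myelin (-0.20 ± 0.10), Abcb1a for endothelium (0.18 ± 0.07), Bmp7 for meninges and fibroblasts (-0.17 ± 0.06) and, near background, Higd1b for pericytes and smooth muscle (-0.17 ± 0.06). Blood lists were led by Slc4a1 for erythroid cells (-0.18 ± 0.10) and, near background, Cpa3 for neutrophils and mast cells (-0.09 ± 0.06). No member of these 18 lists passed among all genes in limma, and 26 had an unadjusted p under 0.05, 3 higher and 23 lower. The skeletal muscle and skin list had a camera adjusted p of 0.385, which became 0.0222 without ethanol array 4.

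Camera adjusted p was under the threshold for 3 of 42 lists, and 6 lists had an unadjusted camera p under 0.05. With an estimated correlation the count was 0 of 42, and fry's directional test also gave 0. Fry's mixed test, which counts changes in either direction without comparison with other genes, was passed by 15 lists. Besides the stress, inflammation and cell type lists named above, these were the glucocorticoid, FoxO, apoptosis, hypoxia, immediate early, circadian, neurotrophin and antioxidant lists. The median, the mean and the camera direction did not all have one sign for hypoxia and glycolysis, synaptic vesicle, postsynaptic density, interferon, chromatin, GABA, ribosomal protein, neurotrophin, cholesterol and antioxidant genes. The same held for olfactory bulb, astrocyte, meningeal, endothelial and myelin markers.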

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

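The count of other splits, both tests on Gh and Cga and the test on Fkbp5, Sgk1 and Tsc22d3 were chosen after the result was seen, and the tests with matched random lists and without saline array 3 before theirs.

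Of 135 sets of 4 saline values examined, 10 held 1 value far from the other 3, where chance gives about 1 in 20, and 7 of the 10 were on saline array 3. The number found is not far above the chance share, and the sets are not independent. On that array the median of tested genes was 8.285, where the next saline array had 8.371, and Slc2a1 was low at 10.07, where the next had 10.29. Over all probesets the median of that array was not the lowest, at 6.84 against 6.83, 6.89 and 6.89 on saline arrays 1, 5 and 6. Its list means were also low for hypoxia and glycolysis (9.812), chromatin and DNA methylation enzymes (9.437), meninges and fibroblast markers (8.49), cholesterol synthesis (9.927) and retinoid signalling (8.181). Ndufa4 was high on saline array 1, at 10.38. On saline array 5, Sdf2l1 was high at 7.45 and Per2 low at 7.679.

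The 12 genes that passed were set against other splits of the 6 arrays into 2 and 4. There are 15 splits, too few for a share under 0.05. The real split gave 12 genes, the highest of the others gave 0, and 1 of the 15 gave as many as 12.

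Gh and Cga were lower on the ethanol arrays and uneven between them. Array scaling is argued against, since the Gh change, which rests partly on a value at background, was still -1.50 under the scaling that left it smallest. Unequal carry-over of pituitary tissue with the brain may account for the pattern: within groups, the deviations of Gh and Cga went together with Pearson r = 0.9845 over 6 arrays (two-sided exact permutation p = 0.0208, the smallest that 48 pairings can give) and Spearman rho = 1 (exact p = 0.0417), both 0.0417 after Benjamini-Hochberg adjustment, for the 1 relation computed. On ethanol array 4 both genes lay within background, at 5.72 and 6.06, so the ethanol deviations are of uncertain size. Without the 2 farthest arrays, both ethanol, r was 0.998. Of 10 pituitary genes with a value, 1 stands in another fixed list, and levels over all arrays averaged 7.70 for Gh, 7.43 for Cga, 6.91 for Ghrhr, 5.48 for Pomc and 5.04 for Prl, the last 2 within background. A lowering of hormone transcripts by ethanol stays open as well, untested.

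The glucocorticoid and FoxO lists were higher on the ethanol arrays. A bias that follows expression level is argued against, because both lists' mean changes lay at percentile 100 of 10000 random lists matched on mean level. Saline array 3 is argued against as the whole cause, because without it the larger of both adjusted p-values from camera was 1.68e-05. Whether the glucocorticoid receptor was more active cannot be told apart from other inputs to these genes: Fkbp5, Sgk1 and Tsc22d3, chosen as close targets, had a mean log2 change of 0.0289 (95% interval -0.11 to 0.17), an interval that holds both 0 and the list median of 0.10. Other effects of the ethanol dose on energy or insulin signalling may contribute and were not tested. Both calls stay open, with unadjusted p of 0.0553 and 0.0835 in camera with an estimated correlation. Members that vary together account for only part of that rise in p. The setting also lowers camera's degrees of freedom to the 4 residual ones of the fit. In the same setting p also rose for pericyte and microglia markers, whose estimated correlations of -0.0023 and -0.0037 lay below the preset 0.01. It did not rise for circadian genes, at -0.0276. The share of the rise that is due to correlation was not tested.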

How the results depend on the processing

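Removing the genes that passed from the called lists, and members of fixed lists or genes with an adjusted p under 0.10 from the added lists, was chosen after the result was seen, and the other alternatives before. No paired analysis was possible because the array numbers are not shared between the groups. The 12 genes kept their sign in each setting that tested them. With limma, the count (higher and lower) was 52 (22 and 30) with the dimmest 50% left out, which tested 11 of the 12 and kept 11, 43 (23 and 20) with a trend in the prior, 56 (21 and 35) with array weights, 23 (17 and 6) after quantile normalization, and 8 (7 and 1) after centring, against 12 (9 and 3) in the main fit. Centring kept 8 of the 12, quantile normalization 11, and trend and weights 12. The count was 0 (0 and 0) over the 26049 probesets that were not dim, where the prior fell to 2.98 degrees of freedom. There, 2570 probesets had an unadjusted p under 0.05. The count was also 0 (0 and 0) with no prior, where 1535 genes had such a p. At an adjusted p under 0.10 it was 95 (40 and 55), and at an unadjusted p under 0.05 with a 1.2-fold change 301 (127 and 174). No filter, probeset means and a robust prior gave 12, 13 and 12. Leaving out 1 array gave 4 to 16 genes (3 to 12 higher and 1 to 5 lower), the fewest without ethanol array 4 and the most without saline array 6. It gave 2 to 4 lists and adjusted p of 2.04e-09 to 2.01e-05 for the glucocorticoid, 5.40e-06 to 0.00358 for the FoxO and 5.10e-06 to 0.0835 for the pituitary list, the last without saline array 3. The number of lists was 0 with an estimated correlation and 0 with fry, where adjusted p of these 3 lists was 0.950 and 0.374 (unadjusted p of 0.0553, 0.0835 and 0.0599 with an estimated correlation, and of 0.0355, 0.0445 and 0.0313 with fry, for the glucocorticoid, FoxO and pituitary lists). Without genes that passed, the glucocorticoid list had 1.09e-06 and the FoxO list 0.00678. Of 1414 other values of the 90 named genes, 1305 kept direction and side of the threshold, 50 lost and 58 gained a call, and 1 reversed, Mog at 0.00828 without ethanol array 2, against -0.20 in the main fit and -0.40 without ethanol array 4. Where no reason is given, the cause was not tested. The robust prior and no prior were not run for lists, since camera has no such setting, and the pituitary list had under 5 members with the dimmest 50% left out. Values near background limit what can be read of 2420 tested genes.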

Other observations

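Both gene lists below, and with them their tests, were chosen after the leading genes had been seen and leave out the genes that prompted them, and the tests with members of fixed lists or with genes of adjusted p under 0.10 removed were chosen after the results for the whole lists were seen.

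Genes that build ribosomes were lower with ethanol as a group. Of 70 tested factors of ribosome biogenesis, 64 lay below 0, with a median log2 change of -0.13, and among them were Wdr75 (-0.27 ± 0.06 SE), Pno1 (-0.27 ± 0.07), Noc3l (-0.26 ± 0.07), Gtpbp4 (-0.25 ± 0.06) and Nop2 (-0.24 ± 0.06). In limma, 16 were lower and 0 higher adjusted over the list alone, and 0 passed among all genes, where Wdr75 had an adjusted p of 0.0953. The hypothesis was that Ltv1, Heatr1, Urb2, Ddx21 and Utp18 stand for a lower expression of the class, and the members of the list went the way it predicts (camera p = 1.57e-11, p = 0.0170 with an estimated correlation, adjusted p = 0.0340 over both added lists). That adjustment covers only the added lists, where the fixed lists were adjusted over 42, so these adjusted p-values cannot be compared. Leaving out 1 array gave camera p of 1.90e-11 to 9.29e-08. Utp18 was itself a gene with an adjusted p under 0.10, as is Wdr75, so the list is not fully apart from the genes that prompted it, and without Wdr75 camera p was 4.99e-11 (p = 0.0170 with an estimated correlation). None of the 70 stands in a list fixed before, and the ribosomal proteins themselves were not shifted. The pattern suggests a lower output of ribosome assembly genes, as a hypothesis found and tested on the same arrays.

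Targets and feedback inhibitors of ERK signalling were lower as a group with camera's preset correlation (p = 2.42e-08), a call that was lost with an estimated correlation (p = 0.0630, adjusted p = 0.0630 over both added lists). All 17 tested members lay below 0, with a median of -0.14, among them Spry4 (-0.49 ± 0.10), Spred3 (-0.39 ± 0.08), Myc (-0.36 ± 0.11) and Dusp7 (-0.26 ± 0.06). In limma, 7 were lower and 0 higher adjusted over the list alone, and 0 passed among all genes, where Spry4 had an adjusted p of 0.0838. The hypothesis was that Dusp6, Etv5 and Nr4a1 were lower because ERK-dependent transcription was, and with the preset correlation camera p was 1.69e-09 to 3.22e-06 with 1 array left out. Of the 17 members, 6, with Spry4 among them, also stand in the neurotrophin list fixed before, so the test is not independent of that list. The remaining 11 all lay below 0, with a median of -0.14, 4 lower adjusted over the list alone and a camera p of 8.16e-06 (lost with an estimated correlation, p = 0.0570, and 3.89e-06 to 0.000193 with 1 array left out). Spry4 and Spred3 have an adjusted p under 0.10 like the genes that prompted the list, and without them camera p was 2.26e-06 (lost with an estimated correlation, p = 0.0853). A lower ERK input may underlie the pattern, which stays open because the call was lost with an estimated correlation. That setting also lowers camera's degrees of freedom to the 4 residual ones, so the loss cannot be put down to correlation alone. The rise of Jun, Dusp1 and Btg2 shows that immediate early genes did not move as 1 group.

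The mean level of the 9 genes that rose was 9.26 and 9.27 on ethanol arrays 2 and 4, and 8.35, 8.28, 8.58 and 8.58 on saline arrays 1, 3, 5 and 6. For the 3 genes that fell it was 7.99 and 7.97 on the ethanol arrays and 8.60, 8.66, 8.48 and 8.56 on the saline arrays. These genes were chosen for their difference on the same arrays, so the separation of the groups adds no support.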
